A study of Homo sapiens with 2 samples.

How the data were processed

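Each of the 2 libraries came with a table of read counts per gene symbol. The deposited values are raw counts, per the file headers, and they are whole numbers with a different total in each library. Per the submitters' processing notes, the tools were Bowtie 0.12.8 and HTSeq and the genome build was hg19; the gene annotation, the counting mode, the treatment of reads with several matches, duplicate removal and strand settings are not given in the sources used here. It is therefore open whether reads were counted over exons or over whole genes, and for genes with at most 2 LIN28 reads the IgG count followed gene span more than transcript length. Results set against transcript length or motif density take the counts as reads of the annotated transcript, which they may not all be. Per the labels' protocols, complexes of LIN28 protein and mRNA were prepared from MCF-7M cells, RNA was purified with phenol and chloroform, and libraries followed Illumina protocols. No row of either table was a total or an unassigned class, and no columns of other samples were present.

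From the counts, CPM were computed with each library's total over genes. The ratio of LIN28 to IgG was the ratio of CPM, and its 95% interval was the exact Clopper-Pearson interval of the 2 counts. Genes with at least 20 counts summed over both libraries were treated as measured. A gene was counted as higher or lower when its ratio was at least 2-fold and the interval excluded 1. With 1 library per antibody there are no residual degrees of freedom among samples, so edgeR, DESeq2 and limma gave no test, and edgeR and DESeq2 were used only for scaling factors. Folds against a count of 0 were computed against a floor of 3 counts in that library and are lower bounds.

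A total of 28 gene lists were fixed before the data were examined, along with the comparisons, thresholds and most alternatives. For each list with at least 5 measured genes, the median log2 ratio (prior count 0.5, in proportion to library size) was set against 10000 random lists with the same number of genes in each of 20 bins of mean log2 CPM, drawn with replacement. Genes were named in the text by a fixed rule, which took LIN28A and LIN28B, the 12 measured genes with the highest lower bound and the 12 with the lowest upper bound of the ratio, the 5 most abundant genes of each library, up to 2 genes at each end of each list, and the measured reported LIN28 targets. That list of targets and the let-7 list were assembled from general knowledge of the field and share 5 measured genes.

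Gene spans, transcript lengths, GC content and motif counts came from GENCODE release 29, which is on GRCh38 and not on the build of the counts, so no coordinates are printed and spans are approximate. Of the symbols, 18316 matched by name and 707 by a RefSeq synonym, and 196 did not match; 99.6% of measured genes had a span. The longest coding transcript stood for each gene, or the longest of any kind where none was coding.

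Alternatives were other scalings (edgeR TMM and upper quartile, DESeq2 size factors, totals without the 10 most abundant genes of each library), minimums of 1 and 100 counts, folds of 1.5 and 4, the LIN28 library thinned to the IgG total, a prior count of 5, and random lists unmatched or matched also on broad groups of transcript length. After the data were seen, an even background per kb of gene span was subtracted (0.0859 reads from the IgG counts, the 10th percentile over genes of at least 100 kb, or the heavier 0.165), genes were limited to spans under 50 kb, and random lists were matched on gene span.

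The interval and list procedures were tested on simulated Poisson counts of the LIN28 against IgG comparison with 200 genes simulated as changed, 190 of them among the 12833 genes that were measured. Of the measured genes simulated at ratios of 0.125, 0.25, 4 and 8, 100%, 97.9%, 100% and 100% were recovered, 0.554% of 12643 unchanged genes were called, and 8 of 200 random lists lay outside the central 95%. The simulation holds counting error only and no spread between immunoprecipitations. It was scaled by the known depths, so it does not test the choice of scaling. Its random lists had no link between ratio and gene length.

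The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.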

Results

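RNA recovered with an antibody against LIN28, an RNA-binding protein that blocks let-7 microRNA maturation and also binds mRNAs, was compared with RNA recovered with a control IgG from the same kind of cells. The cells were MCF-7M, a line whose parent is MCF-7, an estrogen receptor-positive breast cancer line, and they were kept in medium with charcoal-stripped serum. The method, RNA immunoprecipitation followed by sequencing (RIP-seq), pulls down a protein with the RNA bound to it and counts the reads assigned to each gene. One LIN28 library and 1 IgG library were sequenced, so no difference below has a replicate check and no p-value is given. The IgG library held 2783600 reads assigned to genes and the LIN28 library 5384382. Reads were recorded for 19219 gene symbols, of which 2836 had none in either library. Although it was shallower, the IgG library had reads for 16025 genes and the LIN28 library for 14256, or 13645 after the LIN28 library was thinned to the IgG total. A count of 0 allows a level of up to 1.08 CPM (counts scaled to the library total) in the IgG library and 0.557 CPM in the LIN28 library. All intervals are exact 95% intervals that cover counting error only, since reads without molecular identifiers are not independent molecules.

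The comparison asked which mRNAs made up a larger share of the LIN28 library than of the IgG library. The amount of RNA recovered with each antibody did not enter the ratios. A gene with a lower share may therefore still have been recovered in a larger amount with LIN28. Among 12446 genes with at least 20 reads in the 2 libraries together, 1132 were at least 2-fold higher in the LIN28 library and 4652 at least 2-fold lower, each with an interval that excluded a ratio of 1, and 6662 were neither. The median transcript length was 2037 nt for the higher and 4804 nt for the lower genes, and the median gene span 17.3 kb and 86.3 kb. RPS13, a protein of the small ribosomal subunit, was 66.3-fold higher (53.8 to 82.8), with 88 IgG reads and 11291 LIN28 reads. ZYG11B, a substrate receptor of a cullin ubiquitin ligase, was 34.7-fold higher (30.9 to 39.1), S100A9, a calcium-binding protein of myeloid and epithelial cells, 26.3-fold (17.99 to 40.04), and the DNA repair gene MGMT 23.0-fold (19.8 to 26.9). NGDN was 21.2-fold higher (14.3 to 32.9), LYPLAL1 19.5-fold (15.8 to 24.3), and MTFP1, a mitochondrial fission protein, 18.5-fold (13.5 to 26.0). PPP6C, the catalytic subunit of protein phosphatase 6, was 16.5-fold higher (15.4 to 17.7), RPL18 of the large ribosomal subunit 15.4-fold (14.3 to 16.6), THEM5 17.4-fold (12.8 to 24.4) and DUSP12 15.9-fold (12.5 to 20.6). C12orf61 completed the 12 genes with the highest lower bounds, on 1 IgG read against 155 LIN28 reads (80.1-fold, 14.2 to 3185).

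The 12 genes with the lowest upper bounds were long genes with LIN28 counts of 0 to 2, several of them known from neurons. PTPRD, a receptor tyrosine phosphatase, had 376 IgG reads and 1 LIN28 read (727-fold lower, 130 to 28802), DAB1, an adaptor of reelin signalling, 240 against 2 (232-fold lower, 63.6 to 1928), and the adhesion molecule CADM2 173 against 1 (335-fold lower, 59.3 to 13293). TMEM132D had 159 IgG reads and no LIN28 read, which makes it at least 102.5-fold lower against a floor of 3 LIN28 reads. With no LIN28 read either, CNTN4 and SNTG1 were at least 78.7-fold lower, CA10 at least 76.7-fold, UNC13C at least 72.9-fold, PDE1C at least 72.2-fold, RBMS3 at least 67.1-fold, LRRTM4 at least 65.1-fold and CSMD2 at least 64.5-fold. The exact 95% intervals, which are wider than this floor, began at 82.4-fold for TMEM132D, 63.0-fold for CNTN4 and SNTG1, 61.4-fold for CA10 and 51.5-fold for CSMD2. In GENCODE release 29 these genes span between 530 kb (CA10) and 2298 kb (PTPRD), against a median of 38.2 kb for all measured genes. Over the 532 measured genes with at most 2 LIN28 reads and a known span, the IgG library held a median of 0.165 reads per kb of span (interquartile range 0.133 to 0.211). After that density was subtracted from all IgG counts, 2942 genes were at least 2-fold lower. Whether reads in introns were counted is not given in the sources used here, so a count cannot be read as spliced mRNA alone.

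**Figure D1:**
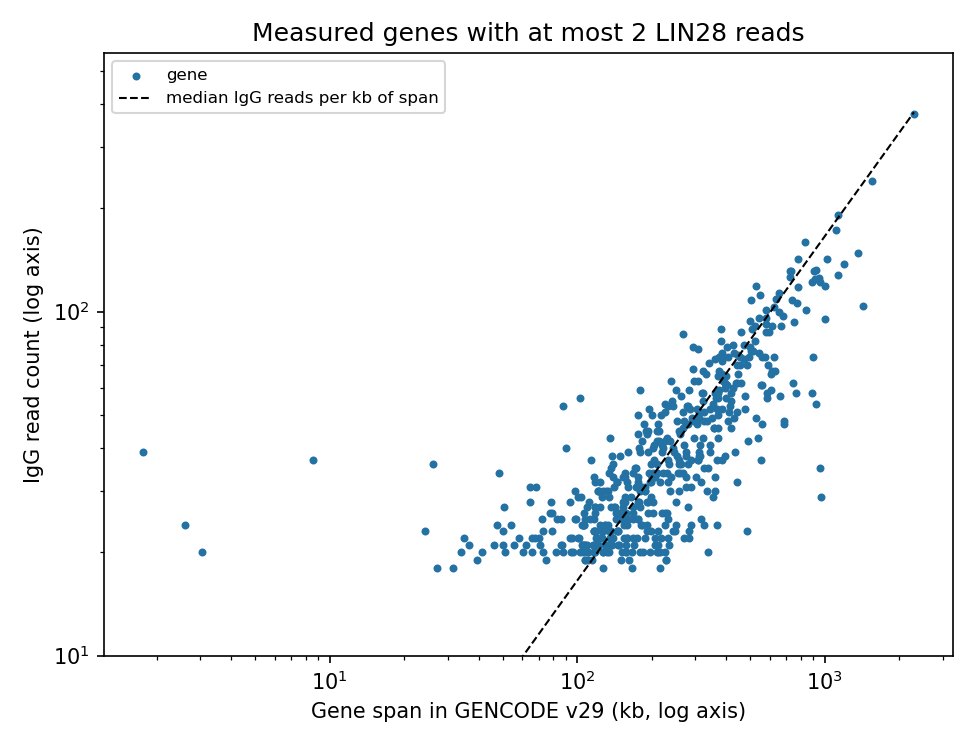
IgG read count (y, log axis) against gene span in kb (x, log axis) for the 532 measured genes with at most 2 LIN28 reads; each point is a gene and the dashed line is the median of 0.165 IgG reads per kb. Most points follow the line, up to PTPRD at 376 reads and 2298 kb, and the lower edge is set by the minimum of 20 reads.

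Ratios were scaled to each library's total, and the median log2 ratio of the measured genes was -0.64, so a typical gene lay below 0. With edgeR's TMM scaling the median was 0.04, every ratio was 1.6 times higher, and 2608 genes were at least 2-fold higher and 2341 lower. Of all genes called, 19.6% were higher with the total, 33.8% with upper-quartile scaling, 52.7% with TMM and 54.2% with DESeq2 size factors. Gene groups are therefore described against random lists of equally abundant genes, and 7 of the 22 groups with at least 5 measured members lay above and 3 below the central 95% of those lists. A scaling factor shifts a list and its random lists alike, so these places hold under the 5 scalings by construction, while the counts of higher and lower genes do not. About 1.1 of 22 would lie outside by chance if members were independent draws at their abundance. Members of a list can share transcript length and gene span, which the ratio followed, so more may lie outside. Of the genes named here as lower, LIN28A, HFM1, EIF4G2, HIST1H3E, KDELR1, MRPS2, MRPS18C, PFKL, RARA, GATA3, HSPA1A, BAG3, PSMC6, IGF2BP2, CCND1 and ERBB2 were less than 2-fold lower with TMM.

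A few genes took a large share of both libraries. HFM1, a meiotic DNA helicase, held 2.95% of IgG reads and 0.931% of LIN28 reads, and PDE3A, a cyclic nucleotide phosphodiesterase, 0.672% and 1.97%. DLG2, a synaptic scaffold protein, held 1.09% of IgG reads, the myosin chaperone UNC45B 0.739% and PID1 0.409%, and these were 4.42-fold, 4.40-fold and 3.82-fold lower in the LIN28 library. The other most abundant LIN28 genes were EMP2, a tetraspan membrane protein, at 5.03-fold higher (4.88 to 5.19), PPP6C, and TMBIM6, an inhibitor of cell death, at 2.24-fold higher (2.17 to 2.30). The 10 most abundant genes held 7.12% of IgG and 6.42% of LIN28 reads. Read positions were not analysed here, so reads stacked at a repeat inside these genes are not separated from recovery of their transcripts.

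The transcript of LIN28A, which encodes a LIN28 protein, had 169 IgG and 137 LIN28 reads and was 2.39-fold lower in the LIN28 library (1.89 to 3.01). With TMM scaling its ratio was 0.671, which is no longer 2-fold lower. LIN28B had 8 IgG reads and 0 LIN28 reads and was too low to be measured. An antibody selects protein, so neither value checks the sample labels. Of 23 measured mRNAs on a list of reported LIN28 targets, 3 were higher, 7 lower and 13 neither. HMGA1, a chromatin architectural protein, was 4.98-fold higher (4.55 to 5.45), the growth factor BMP4 3.48-fold (3.07 to 3.97), and TARDBP, which encodes the splicing regulator TDP-43, 2.13-fold (1.86 to 2.46). Lower were IGF2BP3 (39 IgG reads against 1), INSR (4.23-fold), IGF1R (3.46-fold), IGF2BP2 (2.73-fold), LIN28A, CCND1 (2.08-fold) and ERBB2 (2.0-fold, 1.85 to 2.17). IgG reads per kb of span were 0.243 for IGF2BP3, 0.303 for IGF2BP2, 0.325 for INSR and 0.589 for IGF1R. They were at least 8.92 for LIN28A, CCND1 and ERBB2. After 0.165 IgG reads per kb were subtracted, 4 of 22 measured targets were higher and 5 lower. With TMM scaling the ratios of IGF2BP2, CCND1 and ERBB2 were 0.587, 0.769 and 0.799, no longer 2-fold lower. HNRNPA1 was at a ratio of 1.12 (0.904 to 1.39), FUS at 0.663, HNRNPF at 0.75, TIA1 at 1.61, CDK4 at 0.822, CCNB1 at 1.13, CCNA2 at 1.72, CDK1 at 1.65, CDC20 at 1.45, AKT1 at 0.897, PDPK1 at 0.657, UCP2 at 0.661 and IGF2BP1 at 1.91. The list's median log2 ratio of -0.28 was inside the range of matched random lists (-0.83 to 0.29) and was 0.40 with TMM scaling, where 8 were higher and 3 lower.

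**Figure D2:**
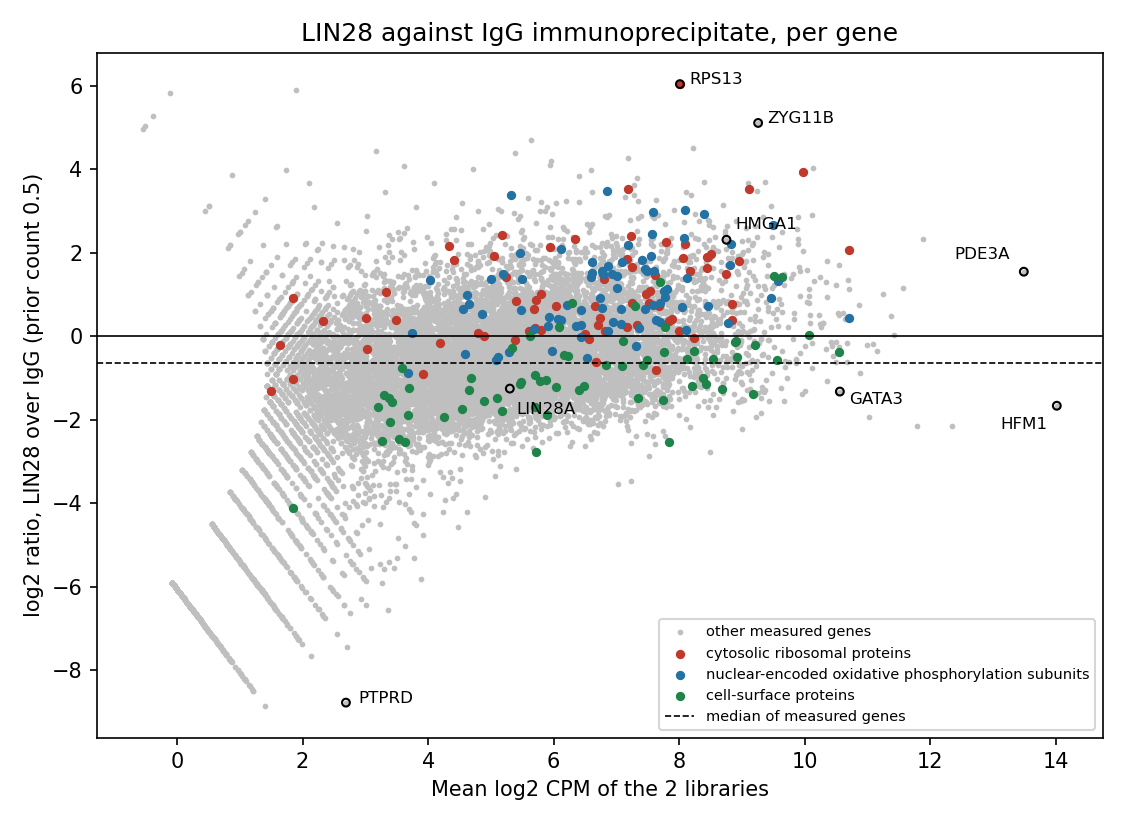
Log2 ratio of LIN28 over IgG (y) against mean log2 CPM of the 2 libraries (x) for 12446 measured genes, each library scaled to its total. Cytosolic ribosomal protein and oxidative phosphorylation genes lie mostly above 0 and cell-surface genes mostly below the dashed median of -0.64; the streaks at lower left are genes with 0 to few LIN28 reads, drawn with a prior count of 0.5.

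Ribosomal protein, oxidative phosphorylation and histone mRNAs had the highest list medians in the LIN28 library. Of 70 measured cytosolic ribosomal protein genes, 31 were at least 2-fold higher, none was 2-fold lower and 39 were neither, and with TMM scaling 48 were higher. Their median log2 ratio of 0.80 lay above all 10000 matched random lists (central 95% -0.58 to 0.05), and their share of reads was 2.57% in the LIN28 library and 0.779% in the IgG library. RPS13 and RPL18 led the group, and RPL28 (ratio 0.573, 0.518 to 0.634) and RPL4 (0.649, 0.563 to 0.748) were at its lower end. Ribosomal protein genes have many near-identical pseudogenes, so single members are uncertain. Of 79 nuclear-encoded oxidative phosphorylation genes, 36 were higher and none lower (61 and none with TMM), with a median log2 ratio of 0.91 against -0.48 to 0.11 in the random lists. Among them, NDUFB3 of complex I was 10.6-fold higher (7.49 to 15.4), UQCRHL, a near copy of the complex III gene UQCRH and therefore uncertain, 11.2-fold (9.13 to 13.9), and SDHD (0.539) and ATP5D (0.694) had the lowest upper bounds. Mitochondrial ribosomal proteins had 24 higher and 2 lower genes of 74 (50 and none with TMM), with a median of 0.64 against -0.61 to -0.02. MRPL44 was 7.05-fold higher (5.21 to 9.77) and MRPL43 6.79-fold (6.12 to 7.56), while MRPS18C was 2.81-fold lower and MRPS2 2.04-fold lower (1.76 to 2.37). The proteasome had 11 higher genes and 1 lower, PSMC6, of 34 (median 0.48 against -0.61 to 0.28; 21 and none with TMM), and PSMA4 was 7.62-fold and PSMB6 7.45-fold higher. The proteasome was inside its random range with matching on transcript length or with spans under 50 kb. Replication-dependent histone genes had 9 higher and 1 lower of 21, or 13 and none with TMM (median 0.71 against -1.63 to -0.36). HIST1H2BC was 3.62-fold higher (2.17 to 6.42) and HIST1H2AB, with 0 IgG and 20 LIN28 reads, at least 3.45-fold higher against a floor of 3 IgG reads, with an exact interval that began at 2.55-fold. HIST1H3E was 2.81-fold lower, and histone genes may also share reads with close copies.

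**Figure D3:**
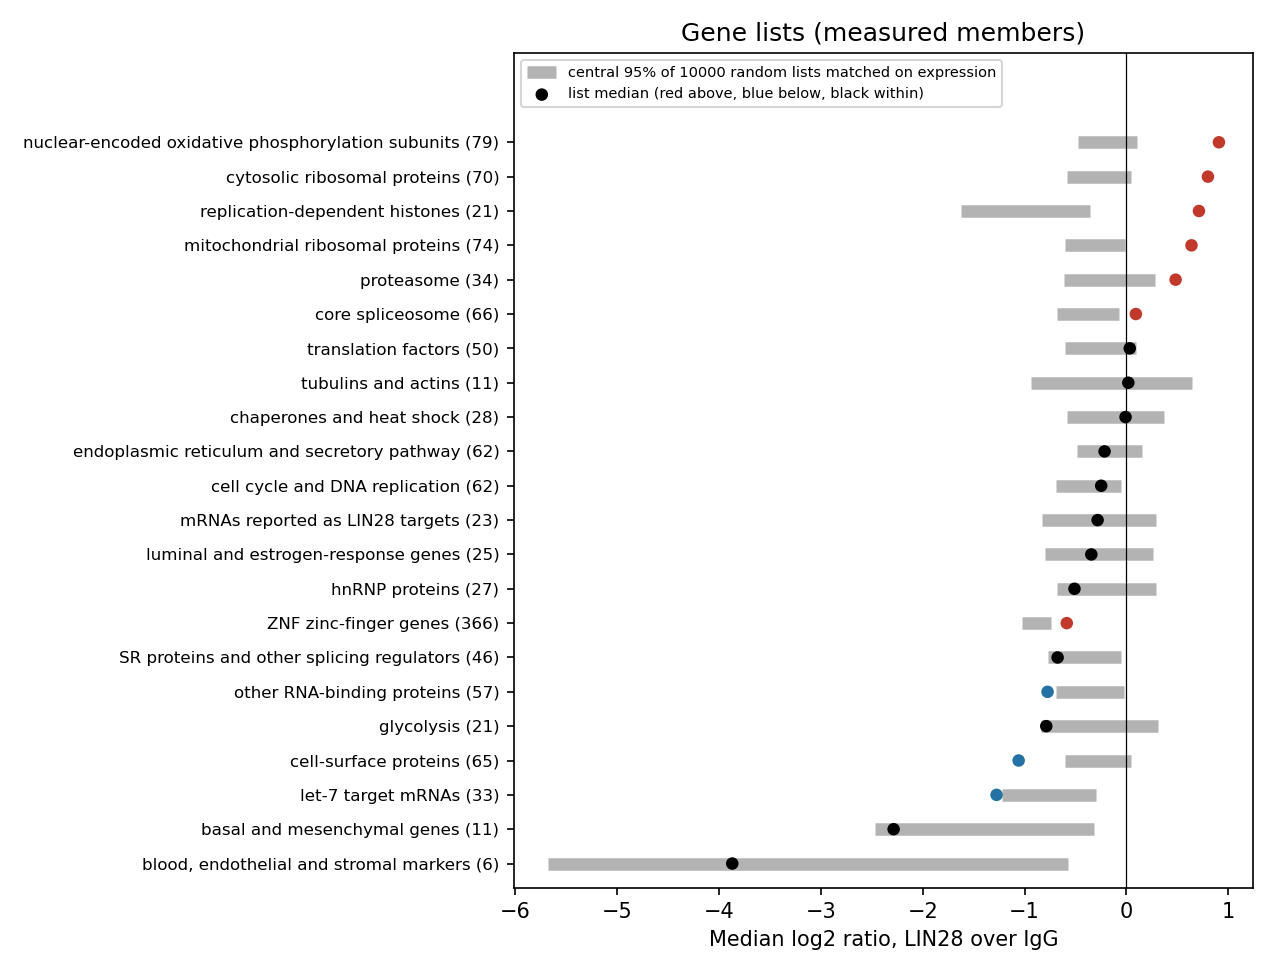
Median log2 ratio of LIN28 over IgG (x) of the 22 gene lists with at least 5 measured members (y, number of measured members in parentheses); grey bars are the central 95% of 10000 random lists matched on expression. Oxidative phosphorylation (0.91) and cytosolic ribosomal proteins (0.80) lie farthest right, and cell-surface proteins (-1.06) lie below their random range.

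Genes of RNA splicing and RNA binding divided. Core spliceosome genes had 16 higher and 12 lower of 66, or 26 and 2 with TMM, with a median of 0.09 against -0.68 to -0.08 in matched lists. SNRNP25 of the minor spliceosome was 10.4-fold higher (9.20 to 11.9) and SNRPB, a Sm protein, 5.62-fold (5.26 to 6.02), while PRPF39 was 4.25-fold and SF3A2 3.75-fold lower. No hnRNP gene of 27 was 2-fold higher and 7 were lower, among them PCBP2 (3.83-fold, 3.61 to 4.07) and the splicing repressor PTBP1 (3.43-fold, 3.04 to 3.87), while HNRNPA0 was at a ratio of 1.51 and RBMX at 1.66. With TMM, 2 hnRNP genes were higher and 4 lower, and the ratios of HNRNPA0 and RBMX were 2.42 and 2.66. The hnRNP median of -0.51 was inside its random range (-0.68 to 0.29) and was 0.17 with TMM scaling. SR proteins and other splicing regulators had 2 higher and 17 lower of 46 (6 and 6 with TMM) and a median of -0.68 (random range -0.77 to -0.05), which was 0.00 with TMM. SRSF9 was 4.57-fold and SRSF3 2.26-fold higher, and SRRM2 5.95-fold and MBNL3 4.66-fold lower. Other RNA-binding proteins, with 4 higher and 19 lower of 57 (10 and 6 with TMM), lay below matched lists (median -0.77 against -0.69 to -0.02), but not with matching on transcript length or unmatched. ILF2 was 3.20-fold and CNBP 2.90-fold higher, and TNRC6B, a scaffold of microRNA silencing, was 7.06-fold and ATXN2 5.43-fold lower. IgG reads per kb of span were 0.289 for TNRC6B and 0.736 for ATXN2. Translation factors had 4 higher and 4 lower of 50 (median 0.03, random range -0.60 to 0.10), but 17 higher and 1 lower with TMM, where the median was 0.71. EEF1G was 7.54-fold and EIF4A1 2.90-fold higher, EIF4G3 4.84-fold (0.337 IgG reads per kb of span) and EIF4G2 2.37-fold lower (280 per kb).

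Cell-surface proteins were the group farthest below its random range, with 35 lower and 3 higher genes of 65 (14 and 5 with TMM) and a median of -1.06, under all 10000 matched lists (-0.60 to 0.05). NOTCH3 was 6.84-fold lower (5.51 to 8.55), and EGFR 19.8-fold lower on 41 IgG and 4 LIN28 reads, a level of 0.213 IgG reads per kb of its span. CD63 (2.75-fold) and LAMP1 (2.68-fold), tetraspanin and lysosomal membrane proteins, were higher. Genes of the endoplasmic reticulum and secretory pathway had 3 higher and 9 lower of 62, or 15 and 1 with TMM, and were inside their random range (median -0.21, range -0.49 to 0.16; 0.46 with TMM). The signal peptidase genes SEC11C (6.93-fold) and SEC11A (3.29-fold) were higher, and RRBP1 (3.52-fold) and KDELR1 (3.14-fold) lower. mRNAs regulated by let-7 had 19 lower and 2 higher genes of 33 (12 and 6 with TMM), and their median of -1.27 was just below matched lists (-1.22 to -0.29). CDK6 had 55 IgG reads and 3 LIN28 reads, at 0.237 IgG reads per kb of span, and IGF2BP3 39 and 1, at 0.243. CDC34 was 2.52-fold and NME6 2.24-fold higher. The list was inside its random range with a minimum of 100 counts, a prior count of 5, background subtraction, or matching on transcript length or gene span. With spans under 50 kb its median of -0.10 was inside the range (-0.89 to 0.51), 0.11 above the random median.

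The remaining groups were inside their random ranges except 1. Zinc-finger genes named ZNF had 24 higher and 110 lower of 366 (63 and 44 with TMM), and their median of -0.59 was above that of equally abundant genes (-1.02 to -0.74) and was 0.09 with TMM scaling. The list did not stand apart with spans under 50 kb, with lists matched on gene span or unmatched, or after subtraction of 0.165 IgG reads per kb. ZNF511 was 8.08-fold and ZNF138 4.49-fold higher, and ZNF423 and ZNF608 had 46 and 28 IgG reads and no LIN28 read. Cell cycle genes had 2 higher and 13 lower of 62 (median -0.25), but 15 higher and 3 lower with TMM (median 0.43), with CDK2 3.01-fold and TYMS 2.26-fold higher and TOP2A 3.28-fold and MKI67 3.22-fold lower. Glycolysis genes had 2 higher and 6 lower of 21 (median -0.79), or 5 and 1 with TMM, with TPI1 6.44-fold and HK1 2.57-fold higher and LDHB 6.13-fold (19 IgG reads, 0.155 per kb of span) and PFKL 2.56-fold lower. Chaperones had 3 higher and 2 lower of 28 (median -0.01), or 10 and none with TMM (0.67). The immunophilin FKBP4 was 2.54-fold and CCT8 2.71-fold higher, and HSPA1A, which may share reads with its copy HSPA1B, 2.66-fold and BAG3 2.11-fold lower. None of 11 tubulin and actin genes differed by 2-fold (median 0.02), TUBA1B being nearest at 1.96-fold higher; with TMM 2 were higher, the median was 0.70 and TUBA1B was 3.14-fold higher. Luminal and estrogen-response genes had 1 higher and 8 lower of 25 (median -0.34), but 5 higher and none lower with TMM (0.33). TFF3 was 2.11-fold higher, KRT18 was at a ratio of 1.75, and RARA (3.19-fold) and GATA3 (2.5-fold, 2.41 to 2.59), a luminal transcription factor, were lower.

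Markers of other cell types were mostly lower in the LIN28 library, but both lists were inside their random ranges. The range was -2.47 to -0.31 for basal and mesenchymal genes. For blood, endothelial and stromal markers it was -5.68 to -0.58. Of 11 measured basal and mesenchymal genes, 9 were lower and none higher (median -2.29; 7 and 1 with TMM), and CDH2 and ZEB1 had 54 and 34 IgG reads, at 0.238 and 0.161 reads per kb of span, and no LIN28 read. S100A4 was at a ratio of 1.56. Of 6 measured blood, endothelial and stromal markers, 4 were lower and none higher (median -3.87, or -3.13 with members at 0 set to 3 reads). ALB had 23 IgG reads, at 0.947 per kb of span, and no LIN28 read. VWF had 32 IgG reads, at 0.182 per kb, and 1 LIN28 read. Genes for mitochondrially encoded, small structural, small nucleolar and long nuclear non-coding RNAs on the lists had no row in the count tables. The microRNA host MIR205HG was at a ratio of 0.969 (0.386 to 2.64) and the snoRNA host TAF1D at 1.15 (0.920 to 1.43).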

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

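Subtracting an even background, limiting genes to spans under 50 kb and matching lists on span were chosen after the data were seen. No paired analysis was possible because each antibody had 1 library, and for the same reason no library could be left out. Genes at least 2-fold higher numbered 1132 with the total, 2608 with TMM, 2701 with DESeq2 size factors, 1714 with upper-quartile scaling, 1831 at a fold of 1.5 and 287 at a fold of 4; all 1132 were also called with each of the first 3 of these scalings. Genes at least 2-fold lower numbered 4652 with the total, 2341 with TMM, 2279 with DESeq2 size factors, 2509 with a minimum of 100 counts, 1744 at a fold of 4, 1714 among genes with spans under 50 kb and 2942 after the heavier background of 0.165 IgG reads per kb was subtracted. Those changes follow from the settings' construction, which shifts every ratio, moves the fold required, tests fewer genes or takes reads from the IgG counts. The other alternatives kept both counts within 1.5 times the main value, including subtraction of the lighter background (1230 higher and 3778 lower). The LIN28A ratio was 0.671 with TMM and 0.687 with DESeq2 size factors, against 0.419 with the total. The ribosomal protein share was 0.731% of IgG and 1.98% of LIN28 reads without the 10 most abundant genes of each library; the share in those genes themselves has no value under that setting. The lists of cytosolic and mitochondrial ribosomal proteins, oxidative phosphorylation, histones and the core spliceosome stayed above, and cell-surface proteins below, their random ranges under every list alternative run, of which the scalings could not move them. The proteasome lost its place with matching on transcript length and spans under 50 kb, the ZNF list with spans under 50 kb, span matching, no matching and the heavier background, and other RNA-binding proteins with length matching and no matching. The let-7 list lost its place under 7 of the list alternatives, namely a minimum of 100 counts, both backgrounds, spans under 50 kb, a prior count of 5, and length and span matching. Basal genes lay below with both backgrounds, a prior count of 5, no matching and span matching, blood and stromal markers with spans under 50 kb, no matching and span matching, and glycolysis with length matching. With no matching, translation factors, secretory pathway, cell cycle and chaperone genes lay above. With genes under 50 kb, the let-7 median moved from below to above its random median, by 0.106, inside the random range; the cause was not tested. No named gene that was called changed direction under the scalings or thinning. Genes near 20 reads can show only large folds, and differences between immunoprecipitations cannot be separated from differences between antibodies.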

Other observations

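Gene families outside the fixed lists were grouped by symbol stem after the data were seen, and 130 families of at least 10 measured genes were set against random lists matched on mean expression and transcript length. Of these, 8 lay above and 12 below the central 95%, where 6.5 in all would lie outside by chance if members were independent draws. Mitochondrial import genes of the TIMM family had 7 of 13 genes higher and none lower (median log2 ratio 1.06, random range -0.51 to 0.78), with TIMM22 12.3-fold higher (10.3 to 14.9). Nudix hydrolases (NUDT) had 7 of 17 higher and none lower (0.64, range -0.71 to 0.39), led by NUDT21, a cleavage and polyadenylation factor, at 7.17-fold (6.21 to 8.31). Actin-related proteins (ACTR) had 3 of 10 higher and 1 lower, METTL methyltransferases 5 of 24 higher and 6 lower, and METTL14, a subunit of the m6A writer, was 18.4-fold higher (4.90 to 154) on 2 IgG and 71 LIN28 reads. Collagens (COL) had 30 of 33 genes lower and none higher (median -5.07, random range -4.49 to -1.84). With members at 0 set to 3 reads the median was -3.83, which has no random range on that scale. Of the 33, 18 had at most 2 LIN28 reads. The family's median IgG density was 0.194 reads per kb of span, against 0.165 for all genes with at most 2 LIN28 reads. Those 18 are among the genes that gave 0.165, so the 2 values are not independent. Axonemal dyneins (DNAH) had 9 of 12 lower, although DNAH12 was 7.87-fold higher (5.73 to 11.1). Cadherins (CDH) outside the lists had 11 of 15 lower and DOCK exchange factors 11 of 11. With random lists matched on gene span, COL (range -4.60 to -2.25), TP, FBXL, IRF, LRRC and KDM stayed below and TIMM, NUDT, ACTR, METTL and NUP above. The other low families, DNAH, CDH, DOCK, SPATA, ARHGAP and PPP, were inside their ranges, as were FBXO, CYB and ALG of the high ones. The median IgG densities of DNAH, CDH and DOCK were 0.189, 0.215 and 0.20 reads per kb. They were 0.480 for ARHGAP, 1.02 for SPATA and 4.18 for PPP. Among TP, FBXL, IRF, LRRC and KDM they ran from 1.84 (KDM) to 29.6 (IRF), so these low families are not all at the background density. TMM scaling adds 0.67 to each log2 ratio, which turns the sign of none of the medians given here, but the counts of higher and lower genes are with the total.

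For the patterns that follow, the tests on genes with at most 2 LIN28 reads and on small RNA genes inside gene bodies, and the subtraction of an even background from the counts of calls, were chosen after the results were seen. The first pattern is the set of genes with IgG reads and few LIN28 reads. Over the 532 genes with at most 2 LIN28 reads, the IgG count followed gene span (Spearman rho across genes 0.793) and much less the transcript length (0.199), as reads spread evenly over gene bodies would give. Genomic DNA or unspliced RNA in the IgG library is a candidate explanation, and these were not tested against each other. The interquartile range was 0.133 to 0.211 IgG reads per kb. Some short genes lay far above it, such as CSH1 (39 reads over 1.75 kb) and ALB (23 over 24.3 kb), so an even spread does not describe all 532. An even background at the densities subtracted here cannot account for all 4652 lower genes. Of these, 3707 were still called after subtraction of 0.0859 IgG reads per kb and 2824 after 0.165. Over 4628 lower genes with a span, rho of the IgG count with span was -0.0715. These values do not test unspliced RNA whose amount differs between genes. Other scalings add nearly 1 shift to all genes, so the lower genes' median of -0.98 with DESeq2 size factors, against -1.69, follows from that shift and tests nothing about them. DESeq2 scaling raised ratios most, by a factor of 1.64, and 2279 of the 4652 genes were still at least 2-fold lower. Those 2279 calls therefore hold under each scaling run, which follows from the size of the factor and tests no larger one. Scaling is left open for the rest. Selective loss of the lower mRNAs with the LIN28 antibody stays open and untested, as 1 library per antibody confounds it with the preparation.

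The second pattern is a lower log2 ratio for longer transcripts (Spearman rho across measured genes -0.44). The median fell from 0.43 in the tenth of genes with the shortest transcripts (median 1156 nt) to -1.49 in the tenth with the longest (9876 nt). The ratio followed gene span as closely (rho -0.441), so this trend does not tell transcript length from span. An even IgG background does not account for the whole trend, since rho was -0.334 after the IgG library's 0.165 reads per kb was subtracted. The median of ribosomal protein mRNAs, 0.80, was at the 99.99th percentile of lists matched on expression and broad groups of transcript length. The random median of 0.15 lay below the 0.43 of the genes with the shortest transcripts. Broad groups may thus leave a difference in length where the ratio changed steeply with it. This match therefore cannot show whether length accounts for all of the higher ratio of ribosomal protein mRNAs. Scaling was not tested by their lowest median over the other scalings, 0.80, since each of these raised the ratios or hardly moved them. RNA fragmentation or size selection that differed between the libraries was not tested and stays open beside LIN28 binding.

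The third pattern is the 100 genes with the highest lower bounds, such as RPS13 with 88 IgG and 11291 LIN28 reads. Reads from small RNA genes inside these gene bodies could supply such counts, as RPS13 hosts snoRNA genes. Of 99 of these genes with a span, 11.1% held a snoRNA, scaRNA, snRNA or other structural RNA gene, against a median of 9.09% and an upper end of the central 95% of 15.2% in random lists matched on expression and span. The share lies between both bounds, so this explanation cannot be told apart from none; read positions, which would show stacks of identical reads, are not in count tables.

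A further hypothesis was that mRNAs richer in GGAGA, a motif that LIN28 proteins are known to bind, are recovered more with the antibody. Across 12390 genes the partial Spearman rho of the log2 ratio with GGAGA per kb of transcript was 0.0369 after ranks of length, GC content and expression were regressed out, and -0.01 before, where at least 0.1 had been predicted. The motif density of whole transcripts therefore carried almost none of the ranking of genes here; genes are not independent replicates, and motif structure and position were not examined.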
